A study of Mus musculus with 10 samples.

How the data were processed

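RNA sequencing had been done on 10 samples whose labels give female Ldlr-/- mice and the thoracic aorta, 5 under an alternate and 5 under a continuous high-fat diet. Ldlr-/- mice lack a working low-density lipoprotein receptor and develop high blood cholesterol and arterial plaques on a fat-rich diet. Per the labels' protocols, total RNA was extracted on Qiagen columns and libraries were made from 100 ng of RNA with Illumina's stranded total RNA kit. Such a kit keeps transcripts without a poly(A) tail and unspliced RNA as well as messenger RNA. STAR 2.7.6a and RSEM 1.3.1 and the builds mm10 and GRCm38 are named in the submitters' processing notes. The annotation release, the strand setting of the counting, read trimming and any filter on reads are not given in the sources used here.

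Each sample had a table of 55487 genes by Ensembl identifier. The expected counts deposited for each gene are RSEM's estimates, which share reads that fit several genes or transcripts among them and need not be whole, per the file headers and the submitters' processing notes. The TPM values deposited beside them are transcripts per 1e6, scaled by the authors' RSEM run for gene length and for the total of each library, per the file headers. The effective lengths deposited there were used only in an alternative. Identifiers were joined to gene names, coordinates and gene types of GENCODE release M21 on GRCm38, and 55227 of them (99.53%) matched. The other 260 held 0.0114% to 0.0262% of the counts of a library and stayed in the totals. Because RSEM divides shared reads, values of near-identical genes, such as Hba-a1 and Hba-a2 or histone genes, are uncertain one by one. Values of antisense and overlapping genes are uncertain too, since the strand setting is not stated.

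Libraries held 12848400 to 21458300 expected counts. A count of 0 allows a level of up to 3 counts, which was 0.140 to 0.233 counts per 1e6 (CPM) depending on the library; such limits cover counting error only. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13806 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), two-sided, with diet as the only term and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05. Fold changes are alternate over continuous, with the standard error derived from the fold change and its F statistic. CPM values are scaled by the same factors. The labels give no batch, litter or pairing, so none entered the model. The sample title numbers fall in 3 separate stretches, the first with 2 continuous, the next with all 5 alternate and the last with 3 continuous libraries. Whether these are batches is not stated; if they are, batch and diet cannot be told apart in any comparison here.

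Before the data were examined, 53 gene lists were fixed, covering leukocyte types, inflammation, smooth muscle, matrix, lipid handling, stress responses and tissues that can be carried over with an aorta. They were chosen for an aortic sample. Of these, 46 had at least 5 tested members and were tested with limma 3.58.1's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the 46 lists. Lists for fibroblasts (4 tested members), lymphatic endothelium (4), brown fat (2), skeletal muscle (2), heart muscle (2), Schwann cells and neurons (2) and mesothelium (0) were left untested. For every tested list a score per library was formed as the mean of its members' log2 CPM, each centred on its mean over the 10 libraries. Scores and library measures were compared by exact two-sided permutation over all 252 assignments of 5 libraries against 5, which cannot give a p under 0.00794. A further 6 lists were added after the data were seen and are reported only among the closing observations.

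Genes named one by one followed a rule that was fixed with the lists. It takes Ldlr, then up to 12 genes per direction past the threshold with a mean CPM of at least 1 and a symbol that is not a predicted gene. As fewer than 5 genes passed, it also takes the 10 genes per direction with the smallest p, given as not passing, 2 to 4 members per described list, and 14 genes set in advance. Markers used to check the labels (such as Myh11, the Y-linked genes, Xist, Mpo, Elane and Prtn3) were chosen after their values were seen. Of the 46 lists, 25 are described singly: the 15 past the threshold and 10 on the subject named in the study's title and diet. The remaining 21, none past the threshold (camera adjusted p from 0.0545 to 0.923), are given only in counts. That choice, and the choice of the lists whose alternatives are printed in full, was made after their values were seen.

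Alternatives covered the normalization (RLE, upper quartile, library size only), the test (DESeq2 1.42.0, limma-voom with and without sample weights, limma on log2(TPM + 1), other edgeR settings), effective-length offsets, the low-count filter, covariates (fat and muscle scores, 1 surrogate variable from sva 3.50.0), the runs of title numbers and leaving out each library. Those on red-cell and long non-coding RNA content were added after the data were seen. The tests were checked on simulated counts for the 13806 genes with these libraries' sizes and spread, 5 against 5. The edgeR step recovered 4% of 50 genes changed 1.5-fold, 44% of 50 changed 2-fold, 98% of 50 changed 4-fold and all 50 changed 8-fold, with 3 false calls. A simulated shift of 0.7 (log2) in the platelet list was recovered by camera and no other list was called. The simulated genes varied independently of each other. The simulation therefore does not show how often camera calls lists falsely where genes vary together.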

Results

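Gene expression was measured by RNA sequencing in 10 libraries labelled as thoracic aorta of female Ldlr-/- mice. The 5 alternate libraries carry the label of a diet with 4 weeks of high-fat feeding from 6 weeks of age, 8 weeks of chow and a final 4 weeks of high-fat feeding. The 5 continuous libraries carry the label of a high-fat diet over the last 8 weeks of the protocol. The comparison addresses whether a second exposure to a high-fat diet gives another transcriptome than an unbroken exposure. The last high-fat period was 4 weeks in the alternate and 8 weeks in the continuous group. A second exposure and a shorter last exposure therefore cannot be told apart. A starting age is given only for the alternate libraries. Total expected counts lay between 12848400 and 21458300, and 18416 to 21257 genes had at least 1 count. The labels do not say that each sample came from a different mouse, so p-values measure the spread between these samples, which may be technical.

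Transcripts that mark the labelled tissue were close to absent. Myh11, the smooth muscle myosin heavy chain, had 12 counts over all 10 libraries, was at 0 in 6 of them and reached at most 0.04 TPM. Tagln and Cnn1, which encode further contractile proteins of smooth muscle, reached 0.41 and 0.19 TPM, and the 3 genes together never exceeded 0.6 TPM in a library. Eln (elastin) reached 0.13 TPM and Col3a1 (type III collagen) 0.12 TPM. Acta2 was higher, at 5.27 ± 0.898 TPM in the alternate and 3.56 ± 2.1 TPM in the continuous libraries (SD, n = 5 each).

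The most abundant transcripts were those of red cells and granulocytes. Hba-a2 averaged 189449 TPM over the 10 libraries and Hba-a1 134915 TPM, although reads of these near-identical α-globin genes cannot be divided with certainty. S100a9 and S100a8, calcium-binding proteins of neutrophils, averaged 51370 and 30046 TPM. Camp, a granule protein of developing neutrophils, averaged 6650 TPM. Mpo, Elane and Prtn3, enzymes made by granulocyte precursors, summed to at least 271 TPM in every library, and the proliferation gene Mki67 lay between 13.2 and 36.3 TPM.

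Y-linked genes were present in all 10 libraries labelled female. Ddx3y had 430 to 971 counts per library, and Ddx3y, Uty, Kdm5d and Eif2s3y summed to 16.7 to 56.3 TPM. Xist, which is transcribed from the inactive X chromosome of female cells, lay between 0.05 and 1.21 TPM. Tissue and sex markers thus went against the labels in both diet groups, and every direction below rests on the diet labels alone. The alternate libraries also form a stretch of title numbers of their own, so a batch, if the stretches are batches, would go with diet.

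**Figure D1:**
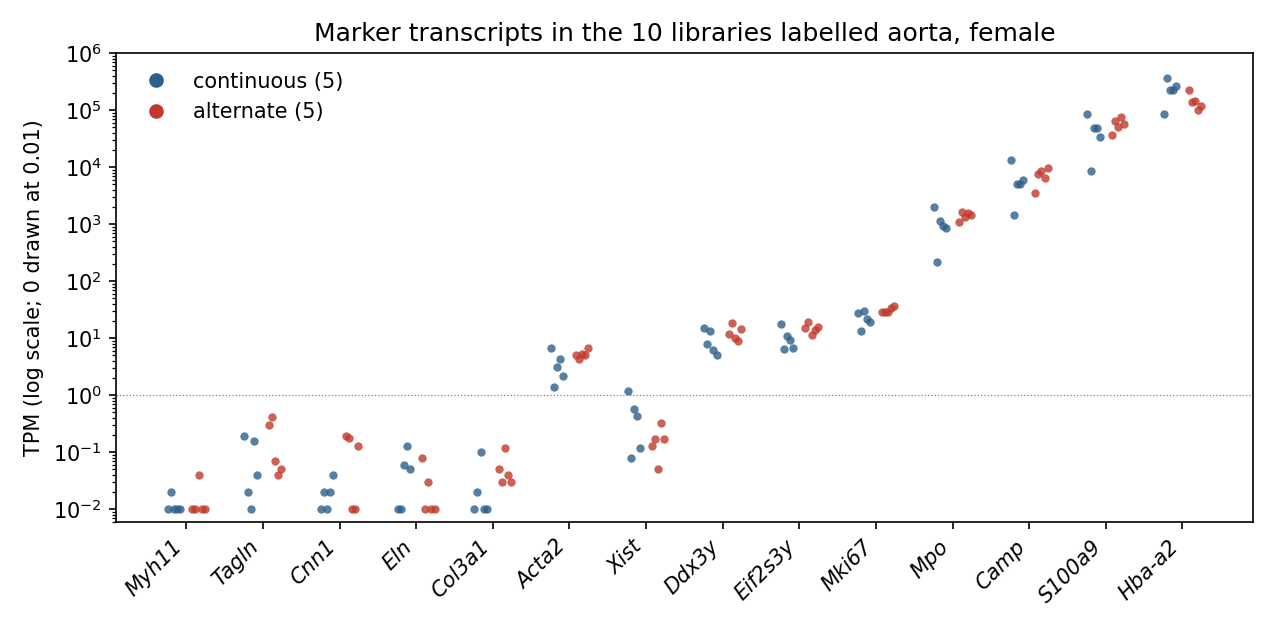
Abundance of marker transcripts in each library, in TPM on a log scale with 0 drawn at 0.01; each point is 1 library, 5 continuous and 5 alternate. Myh11 stays at or under 0.04 TPM, whereas Ddx3y has at least 4.98 TPM and S100a9 at least 8668 TPM in every library.

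Ldlr, the gene disrupted in these mice, had 0.562 ± 0.248 TPM in the alternate and 0.43 ± 0.261 TPM in the continuous libraries (SD, n = 5 each), from 13 to 46 counts per library. No library without the disruption was analysed here, and a count over the whole gene does not show whether its disrupted part was transcribed, so this value does not check the genotype. The groups did not differ in Ldlr (log2 fold change -0.07 ± 0.40 SE, edgeR adjusted p = 1.0).

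Red-cell transcripts took unlike shares of the libraries. The 4 globin genes took 18.8% ± 5.48 of counts in the alternate and 33.9% ± 16.7 in the continuous libraries (SD, n = 5 each), a difference of -15.1 percentage points that did not pass an exact permutation test (p = 0.0873, adjusted p = 0.310). Continuous library 2 had the highest share (55.8%) and continuous library 1 the lowest (10.4%). Without continuous library 2 the difference was -9.64 percentage points (exact permutation p = 0.175). The 50 most abundant genes took 42% ± 3.95 of counts against 55.3% ± 12.1 (exact permutation p = 0.0397, adjusted p = 0.310). The TMM scaling factors were 1.16 ± 0.0863 in the alternate and 0.890 ± 0.244 in the continuous libraries (exact permutation p = 0.0476, adjusted p = 0.310). Mitochondrial transcripts took 4.51% ± 1.49 against 6.13% ± 2.32 (exact permutation p = 0.214). Of the tissues that can be carried over with an aorta, white fat and thymus scores did not differ (exact permutation p = 0.119 and 0.238). The white fat score rested on 7 of the list's 14 genes. Adipoq, Plin1, Lep and Cidec were not among the genes tested, so the score says little about carried-over fat.

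Of 13806 genes tested, 1 was higher and 0 were lower in the alternate libraries. The gene was Ppbp, which encodes a CXC chemokine stored in platelet granules (ENSMUSG00000029372, a protein-coding gene at chromosome 5, 90768518 to 90770063, forward strand, GRCm38). Ppbp had 126 ± 26.7 CPM in the alternate and 37.7 ± 9.12 CPM in the continuous libraries (SD, n = 5 each), and the groups did not overlap, with 84.7 CPM as the lowest alternate and 49.8 CPM as the highest continuous value. Its log2 fold change was 1.74 ± 0.21 (SE; 95% interval 1.29 to 2.19; edgeR quasi-likelihood test, adjusted p = 0.0109), and 5 of 5 alternate libraries lay above the continuous mean. At an unadjusted p under 0.05 there were 789 genes, 346 higher and 443 lower, where chance gives 690. DESeq2 called 18 genes, 14 higher and 4 lower, limma on log2(TPM + 1) called 0, and edgeR without the low-count filter called 17. Over 33 alternatives the adjusted p of Ppbp ran from 4.81e-11 (DESeq2) to 0.695 (edgeR, 2 continuous libraries), and 26 of them kept it past the threshold. It lost the edgeR threshold without continuous library 2 (adjusted p = 0.0576) and without continuous library 5 (0.0529), where the count was 0, and the count became 3 without alternate library 1, 2 without alternate library 4 and 5 without continuous library 1.

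Genes next in rank did not pass the edgeR threshold. The higher ones included Slc6a4, the serotonin transporter (log2 fold change 2.19 ± 0.38 SE), Alox12, arachidonate 12-lipoxygenase (1.59 ± 0.36), F13a1, coagulation factor XIII (0.84 ± 0.18) and Vwf, von Willebrand factor (0.84 ± 0.18), with edgeR adjusted p between 0.134 and 0.574. Lifr (1.42 ± 0.22), Mylk (1.46 ± 0.26), the interferon-inducible genes Ifi211 (1.10 ± 0.20) and Ifi207 (1.04 ± 0.21) and Ms4a6b (0.91 ± 0.19) completed this set, with edgeR adjusted p from 0.113 for Lifr to 0.380. The lower ones included Chpf2 (-2.36 ± 0.40, edgeR adjusted p = 0.134), Col1a1, a chain of type I collagen (-1.73 ± 0.45), Igha, the immunoglobulin A heavy chain (-1.21 ± 0.35), and Bpgm, the enzyme of 2,3-bisphosphoglycerate synthesis in red cells (-1.73 ± 0.49). Ccndbp1 (-1.28 ± 0.33), Pim2 (-1.21 ± 0.32), Hist2h3b (-1.45 ± 0.39), Fam213a (-1.54 ± 0.43), Adipor1 (-0.67 ± 0.19) and AC149090.1 (-0.57 ± 0.16) had an edgeR adjusted p of 0.830, as had Col1a1, Igha and Bpgm. Without continuous library 2, Ccndbp1 was -0.85, Bpgm -1.22, Fam213a -1.09, Hist2h3b -1.18, Col1a1 -1.46, Adipor1 -0.51 and AC149090.1 -0.50. These were the weakest values of each gene when any 1 library was left out. Pim2 and Igha were weakest without continuous library 5 and Chpf2 without alternate library 1. Under DESeq2, Slc6a4, Lifr, Mylk, Ifi211, Ifi207, Ms4a6b, Vwf, F13a1, Alox12, Chpf2, Ccndbp1 and Col1a1 were among those called. By edgeR, Slc6a4 (adjusted p = 0.0466) and Mylk (0.0330) passed without alternate library 1, and Chpf2 (0.0397) without continuous library 1.

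The platelet list was higher in the alternate libraries. Its score was 0.32 ± 0.23 in the alternate and -0.32 ± 0.11 in the continuous libraries (SD, n = 5 each), a difference of 0.63 with an exact permutation p of 0.00794 (the smallest that 5 libraries against 5 can give). Over all genes 1 of its 7 members passed the edgeR test, and adjusted over the list alone 3 were higher: Ppbp, Treml1, a receptor of platelet granules (log2 fold change 0.99), and Itgb3, the integrin β3 chain (0.43). Gp9 (0.71), Itga2b (0.36), Pf4 (0.16) and Gp1bb (-0.01) did not pass. The list had a camera adjusted p of 1.56e-05, and an adjusted p of 0.127 with an estimated correlation. Without Ppbp the 6 other members still gave a score difference of 0.45 (exact permutation p = 0.0159).

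**Figure D2:**
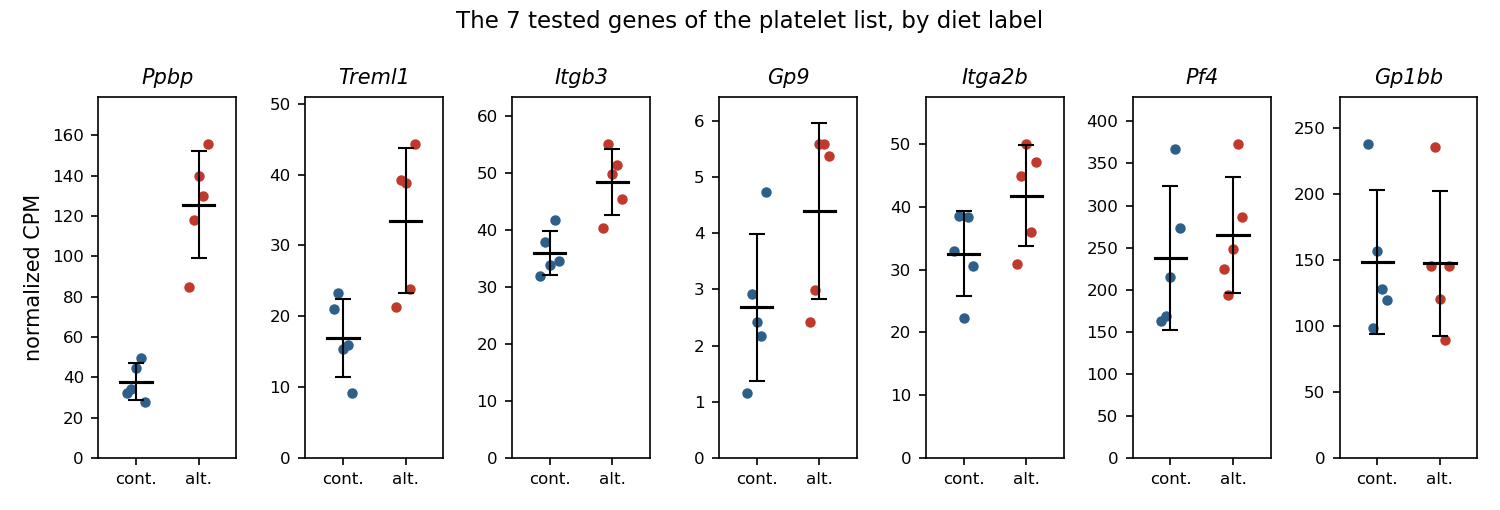
Normalized CPM of the 7 tested platelet-list genes, 1 point per library, with the mean (wide bar) and SD (error bars) of the 5 continuous and 5 alternate libraries. Ppbp separates the groups (27.8 to 49.8 CPM against 84.7 to 156 CPM), while Pf4 and Gp1bb overlap.

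Of 46 lists tested by camera, 15 passed, 10 higher and 5 lower in the alternate libraries; over 100 groupings of the same libraries the median was 8 lists. With an estimated correlation 0 passed and 6 had an unadjusted p under 0.05. The limma fry test called 5. Of these, 4 were among the 15 and 1, replication histones (fry adjusted p = 0.0493), was not. Exact permutation of the list scores called 0 after adjustment, with 8 under an unadjusted p of 0.05. The smallest possible exact permutation p, 0.00794, can pass adjustment over 46 lists only where several lists reach it. This count of 0 therefore says little about any single list.

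Chemokine genes were higher as a list (score difference 0.52, exact permutation p = 0.00794; camera adjusted p = 0.00189, and adjusted p = 0.127 with an estimated correlation). Of 12 tested members 0 passed over all genes and 1 was higher adjusted over the list alone, the neutrophil attractant Cxcl2 (log2 fold change 1.79). Ccl9 (0.49), Ccl4 (0.79) and Ccl2 (1.70) did not pass. The camera call was lost without continuous library 3 (adjusted p = 0.0545). Monocyte genes gave a score difference of 0.44 (exact permutation p = 0.0397; camera adjusted p = 0.00314, and adjusted p = 0.365 with an estimated correlation). Of 12 members 0 passed over all genes, and Vcan (1.57) and Ccr2, the receptor of Ccl2 (0.87), were higher adjusted over the list alone. The camera call ended against the earlier continuous run of title numbers (adjusted p = 0.0998) and with the red-cell score as covariate (0.163), in a range of 0.000342 to 0.365 over 20 alternatives.

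Immediate-early genes, which are induced within minutes of stimulation or handling, were higher as a list (camera adjusted p = 7.27e-06, and adjusted p = 0.365 with an estimated correlation; score difference 0.47, exact permutation p = 0.0397). Of 21 tested members 0 passed over all genes and Klf4 (log2 fold change 1.12) passed adjusted over the list alone; Egr1 (1.17) and Jun (0.85) did not. Against the earlier continuous run of title numbers alone the camera call was lost (adjusted p = 0.277; 5.61e-08 to 0.365 over 20 alternatives). Interferon-response genes had a camera adjusted p of 4.25e-05, and an adjusted p of 0.365 with an estimated correlation. Of 21 members 19 had a positive fold change, 0 passed over all genes or adjusted over the list alone, and the exact permutation p of the score was 0.119. Genes of the endoplasmic reticulum stress response (Pdia4 1.04, Dnajc3 0.52; 0 of 17 past either test) had a camera adjusted p of 0.00595, and an adjusted p of 0.431 with an estimated correlation. That call was lost without alternate library 4 (0.0636) and against the later continuous run (0.111), with camera adjusted p of 0.000626 to 0.431 over 20 alternatives.

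Another 3 lists named for vessel wall cells were called higher in the alternate libraries by camera. In the order below, the exact permutation p of their scores were 0.00794, 0.0159 and 0.0238 (adjusted p = 0.122, 0.183 and 0.183). In that order, 7 of 17, 8 of 19 and 11 of 17 members were tested. Positive fold changes numbered 6, 5 and 6, and negative ones 1, 3 and 5. The median log2 fold change of the endothelial list was 0.07. In the list of modulated, cartilage-like smooth muscle, Klf4 (1.12) and Spp1, osteopontin (1.08), were higher adjusted over the list alone, 0 of 7 passed over all genes, and the camera adjusted p was 0.00437, or an adjusted p of 0.130 with an estimated correlation. Klf4 also stands in the immediate-early list. In the contractile smooth muscle list Mylk (1.46) and Cald1 (1.11) were higher adjusted over the list alone, 0 of 8 passed over all genes, and Acta2 (0.13) did not pass. Its camera adjusted p was 0.0165 and its adjusted p 0.202 with an estimated correlation, and the call was lost without continuous library 1 (0.0846), against the earlier continuous run (0.277) and without the 4 libraries lowest in long non-coding RNA (0.161), in a range from 0.00249 to 0.277. Myosin light chain kinase (Mylk) and caldesmon (Cald1) are also made by non-muscle cells. In the endothelial list Vwf (0.84), Esam (1.56) and Cdh5, the endothelial cadherin (1.81, from at most 23 counts per library), were higher adjusted over the list alone and 0 of 11 passed over all genes. Vwf and Esam are also found in platelets. The camera adjusted p was 0.0316, with an adjusted p of 0.365 under an estimated correlation, and the call was lost when any of 6 libraries was left out: without alternate library 1 (0.0634), 3 (0.099) or 5 (0.0537), or without continuous library 1 (0.0992), 3 (0.135) or 5 (0.0639). It was also lost among genes with a mean CPM of at least 1 (camera adjusted p = 0.146), against the earlier continuous run (0.291) and without the 4 libraries lowest in long non-coding RNA (0.379), in a range from 0.00226 to 0.379.

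Red-cell genes were lower as a list in the alternate libraries, alongside the globin shares given above. All 7 members had negative fold changes, 0 passed over all genes, and 6 were lower adjusted over the list alone, including Hbb-bs (log2 fold change -1.57) and Alas2, the first enzyme of haem synthesis in red cells (-1.35). The camera adjusted p was 3.69e-05, and an adjusted p of 0.365 with an estimated correlation. The score was -0.50 ± 0.51 against 0.50 ± 1.09 (SD, n = 5 each) and had an exact permutation p of 0.0952. Mitochondrially encoded genes moved the same way: all 13 had negative fold changes, 10 were lower adjusted over the list alone (mt-Nd3 -1.25, mt-Co2 -1.22), 0 passed over all genes, and the camera adjusted p was 2.08e-08, or an adjusted p of 0.365 with an estimated correlation (exact permutation p of the score = 0.0952). Scaling by library size alone moved the median of all genes by 0.39 (log2) and left both lists at a negative mean.

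B-cell and plasma-cell genes (14 of 15 negative; Cd79b -0.99, Cd19 -1.02), T-cell genes (16 of 19 negative; Ccr7 -0.78, Cd2 -0.75) and thymocyte genes (9 of 9 negative; Themis -1.38, Rag1 -0.65) had camera adjusted p of 0.0107, 0.0175 and 0.0414. Tcf7 and Cd8b1 stand in both the T-cell and the thymocyte list, so these are not separate results. In none of these lists did a member pass over all genes or adjusted over the list alone, and the adjusted p were 0.636, 0.504 and 0.504 with an estimated correlation. Exact permutation p of the scores were 0.413, 0.238 and 0.238. Scaling by library size alone turned the mean fold change of the T-cell list to 0.13 and moved those of the B-cell and thymocyte lists to -0.02 and -0.03. The median of all genes moved to 0.39 under that scaling, so all 3 means stayed below it. Leaving out continuous library 2 ended the 3 calls (camera adjusted p = 0.389, 0.272 and 0.410), as did leaving out alternate library 2 (0.259, 0.179 and 0.107). The B-cell call also ended without continuous library 5 (0.0639), the T-cell call without alternate library 1 (0.0780) or continuous library 5 (0.0640), and the thymocyte call without alternate library 4 (0.108) or continuous library 3 (0.0542). The earlier continuous run alone ended the B-cell (camera adjusted p = 0.228) and thymocyte calls (0.0791) and the later one the T-cell call (0.0837). Among genes with a mean CPM of at least 1 the T-cell (camera adjusted p = 0.0647) and thymocyte calls (0.298) ended, and the fat covariate ended the T-cell call (0.0869). Over 20 alternatives camera's adjusted p ran from 0.00254 to 0.984 for T-cell genes. For thymocyte genes the adjusted p ran from 3.54e-05 to 0.573, the highest being that of fry. With the red-cell score as a covariate the B-cell list was higher in the alternate libraries (camera adjusted p = 0.0113; 3.46e-08 to 0.636 over 20 alternatives). Lysosomal genes (Ctsz 0.36, Lamp2 0.41; 0 of 22 past either test) had a camera adjusted p of 0.0316, and an adjusted p of 0.560 with an estimated correlation. That call ended without alternate library 2 (0.107), 3 (0.099) or 4 (0.0516) or continuous library 2 (0.279) or 3 (0.158), and against the earlier continuous run (0.332), in a range from 0.00128 to 0.841.

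**Figure D3:**
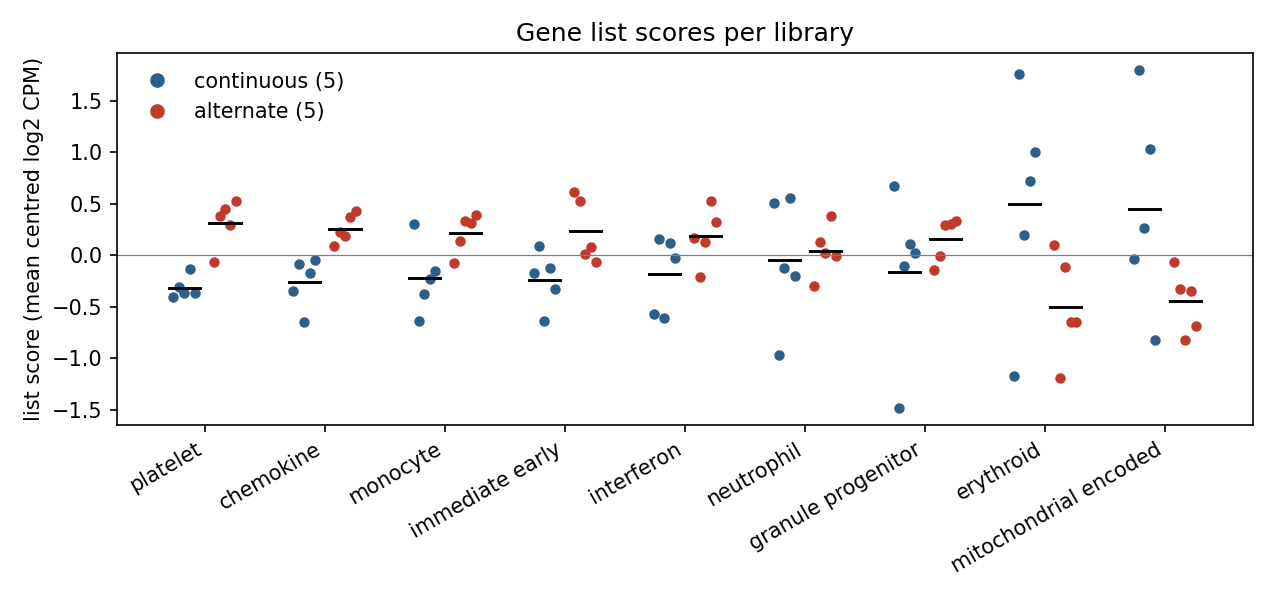
Scores of 9 gene lists in each library, as the mean of centred log2 CPM; points are libraries and bars are group means over 5 continuous and 5 alternate libraries. Platelet scores lie higher in the alternate libraries (mean 0.32 against -0.32), and red-cell scores spread most within the continuous group (SD 1.09).

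Neutrophil genes, the cell type named in the study's title, did not differ as a list: 10 of 19 members had positive and 9 negative fold changes, the score difference was 0.09 and its exact permutation p 0.778 (camera adjusted p = 0.499). The call depended on the covariate, since with the red-cell score in the model the list was lower in the alternate libraries (camera adjusted p = 0.00191), and without continuous library 4 it was higher (0.0374), against 0.00191 to 0.967 over 20 alternatives in both directions. S100a8 (log2 fold change 0.28 ± 0.44 SE), S100a9 (-0.05 ± 0.36) and Cxcr2, the receptor of neutrophil chemokines (0.25 ± 0.35), did not pass (edgeR adjusted p = 1.0 each). S100a8 was 0.04 without continuous library 2 and 0.62 without continuous library 1, S100a9 -0.26 without continuous library 2 and 0.08 without continuous library 4, and Cxcr2 0.05 and 0.54 without the same 2 libraries. The granulocyte precursor list had positive values for Prtn3 (0.46), Elane (0.47) and Mpo (0.25) but did not pass (camera adjusted p = 0.0790, exact permutation p of the score = 0.540). With the red-cell score as covariate it was lower (camera adjusted p = 0.0482). It passed as higher without alternate library 1 (0.0437), continuous library 1 (0.00335) or continuous library 4 (0.0343), against the earlier run of title numbers (0.0306) and without the 4 libraries lowest in long non-coding RNA (0.00919), and ran up to 0.758 over 20 alternatives.

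Interleukin-1 and inflammasome genes did not pass (camera adjusted p = 0.472; 0 of 14 members), and Il1b itself had 82.5 ± 29.4 CPM in the alternate and 121 ± 50.8 CPM in the continuous libraries (SD, n = 5 each; log2 fold change -0.55 ± 0.29 SE, edgeR adjusted p = 0.931; -0.28 without continuous library 1). NF-κB targets (camera adjusted p = 0.843), leukocyte adhesion (0.273), cholesterol synthesis (0.251), cholesterol efflux (0.923) and proliferation genes (0.866) did not pass, nor did general (0.0980) and foamy macrophage genes (0.156). The cholesterol efflux list had a negative mean and camera direction beside a score difference of 0.01. General macrophage genes passed as higher without continuous library 4 (camera adjusted p = 0.0152) and against the earlier run of title numbers (0.0306), with up to 0.596 over 20 alternatives. Foamy macrophage genes passed without alternate library 1 (0.0317, up to 0.688), and cholesterol synthesis genes without the 4 libraries lowest in long non-coding RNA (0.0197, up to 0.987). Spp1 (1.08 ± 0.37 SE), Ccl2 (1.70 ± 0.72), Cd68 (0.35 ± 0.22), Trem2 (0.30 ± 0.34), Runx1 (0.24 ± 0.15), Acta2 (0.13 ± 0.24) and Vcam1 (-0.29 ± 0.15) had edgeR adjusted p of 0.830 or above. Cd68 was 0.17 without alternate library 4, Trem2 0.11 without continuous library 3 and 0.49 without continuous library 1, and Acta2 0.04 without continuous library 5 and 0.30 without continuous library 4. Myh11 and Cxcl1 had too few counts to be tested.

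Libraries did not separate by diet as a whole. The first principal component held 27.8% of the variance (exact permutation p = 0.516 between diets) and none of the first 4 components differed (exact permutation p = 0.0873 or above). Rank correlations of log2 CPM lay between 0.916 and 0.982 within diets and between 0.927 and 0.974 across diets. Every pair of libraries differed by far more than counting error alone (at least 22.2 chi-square units per gene), so each was counted as a separate library. Counting error leaves out differences of library preparation, so this does not show that the libraries came from different mice.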

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

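The tests of explanations for tissue, sex and platelet genes were chosen only after the results were seen. Earlier forms of the platelet tests on Ppbp alone, and of the structure test on groups defined by its outcome, were run first and replaced. A contrast of platelet genes with the mean of 7 white-cell lists was dropped, because those lists went opposite ways, and the bound of 0 for the red-cell covariate was added after the bound of 0.316 had left the question open.

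In a test of 1 library far from the 4 others of its diet, 5 of 126 groups stood out, where chance gives about 6. Alternate library 2 had 7.12% mitochondrial counts (others 3.39% to 4.21%) and 0.632 CPM of Col1a1 (2.36 to 2.99). Continuous library 5 had 1333 CPM of Igha (463 to 623), continuous library 3 had 39.96 CPM of Runx1 (31.3 to 32.9), and alternate library 1 had a lysosome score of -0.0604 (0.10 to 0.15). A signal outside the main comparison was present in all 10 libraries: at least 430 counts of the Y-linked gene Ddx3y under a female label, and at least 3674 counts of Mpo under an aorta label.

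Tissue and sex markers went against the labels. The highest sum of Myh11, Tagln and Cnn1 was 0.6 TPM, where above 10 TPM was set for an aortic wall after the values were seen. That sum argues against blood or marrow cells carried over with an aortic wall. The summed Y-linked genes were at least 37.4 times Xist, which argues against female cells with a small share of male cells. Mpo, Elane and Prtn3 reached at least 271 TPM in every library, so the files could come from a blood-forming tissue of male mice under other labels, which remains a hypothesis. These explanations all concern sampling or labelling; the design gives no biological one for the markers, so none was tested.

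Platelet genes were higher in the alternate libraries by camera. However, they had an adjusted p of 0.127 with an estimated correlation and an adjusted exact permutation p of 0.122 for their score. The unadjusted exact permutation p of the score, 0.00794, was the smallest possible. Its adjusted value therefore depended on how many of the 46 lists reached that p. With the red-cell score as covariate the difference was 0.623 (0.632 before) and the lower end of its 95% interval 0.276, which argues against fewer red-cell transcripts as the whole cause; the interval also held 0.316, so red cells as the cause of most of it stayed open. The continuous title numbers fall in an earlier and a later stretch, and neither alone carried the pattern. The difference was 0.604 against the later (exact permutation p = 0.0179) and 0.674 against the earlier (exact permutation p = 0.0476). Each p was the smallest that so few libraries can give. All 5 alternate libraries form a stretch of their own, so an effect of that stretch cannot be told apart from diet. More platelets of an unchanged make-up stayed open, because the variance between members lay above that of other assignments with Ppbp (exact permutation p = 0.00794) but not without it (0.214), and no table shows which cells the transcripts came from. An added megakaryocyte list outside the platelet list was higher too (difference 0.43, exact permutation p = 0.00794; camera adjusted p = 0.0571 with an estimated correlation), which may reflect the diet named by the labels or any other difference between the groups.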

How the results depend on the processing

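The alternatives on red-cell and long non-coding RNA content, the removal of globin and mitochondrial genes and the title-number runs for the lists were chosen only after the results were seen; the others were not. No paired analysis was possible because the labels number no replicates shared between the diets. The gene count of 1 became 4 (library size only), 18 (DESeq2), 0 (limma on TPM), 17 (no filter), 0 against the later and 0 against the earlier continuous run, 2 (fat covariate), 3 (surrogate variable), 0 (red-cell covariate), 3 (long non-coding RNA covariate) and 0 without the 4 libraries lowest in long non-coding RNA; leaving out 1 library gave 0 to 5. Ppbp stayed higher in all 33 alternatives and lost the threshold at a log2 fold change of 2.27 (limma on TPM), 1.63 (later run), 1.92 (earlier run), 1.70 (red-cell covariate) and 1.37 (without the 4 libraries); leaving out 1 library gave 1.64 to 1.86. The 15 lists became 0 with an estimated correlation (adjusted p: monocyte 0.365, red-cell 0.365, chemokine 0.127, platelet 0.127) and 5 with fry, 4 of them among the 15 and 1 new, replication histones (monocyte 0.260, red-cell 0.380). With the red-cell covariate Ppbp was 1.70 ± 0.27 (SE) after 1.74 ± 0.21. There camera's adjusted p was 0.163 for monocyte genes and, fixed by the covariate being their own score, 0.987 for red-cell genes, and the direction turned for T-cell (0.984), B-cell (0.0113), thymocyte (0.486), lysosome (0.841), neutrophil (0.00191), granulocyte precursor (0.0482), interleukin-1 (0.841), NF-κB (0.922), proliferation (0.0907) and cholesterol synthesis genes (0.987). Without the 4 libraries proliferation turned (camera adjusted p = 0.947) and contractile (0.161) and endothelial genes (0.379) lost their calls. Against the later run neutrophil genes turned (camera adjusted p = 0.708) and T-cell (0.0837) and endoplasmic reticulum stress genes (0.111) lost theirs. Against the earlier run calls ended for monocyte (camera adjusted p = 0.0998), thymocyte (0.0791), B-cell (0.228), immediate-early (0.277), contractile (0.277), endothelial (0.291) and lysosome genes (0.332), and interleukin-1 (0.773), NF-κB (0.667), proliferation (0.277) and cholesterol efflux genes (0.848) turned. Leaving out 1 library turned some directions: camera adjusted p ran 0.741 to 0.9998 (cholesterol efflux), 0.00335 to 0.758 (granulocyte precursor), 0.0374 to 0.967 (neutrophil), 0.536 to 0.9998 (NF-κB) and 0.337 to 0.968 (proliferation); for chemokine genes it ran 0.00103 to 0.0545. Log2 fold changes ran -0.23 to 0.14 (Ldlr), -0.26 to 0.082 (S100a9), 0.04 to 0.62 (S100a8), 0.05 to 0.54 (Cxcr2), -0.72 to -0.28 (Il1b), 0.17 to 0.48 (Cd68), 0.11 to 0.49 (Trem2), 0.04 to 0.30 (Acta2) and -1.47 to -0.85 (Ccndbp1). Library size alone moved the median log2 fold change of all genes to 0.39 and with it turned Ldlr (0.26), S100a9 (0.25) and Vcam1 (0.12). It also turned the mean fold changes of the T-cell (0.13), proliferation (0.37) and cholesterol efflux lists (0.34). All of these stayed below that median. The neutrophil mean ran -0.00098 to 0.33 over scalings. Scores of carried-over tissue from log2(TPM + 1) gave 1 difference at an unadjusted exact permutation p under 0.05 (0.0476), in place of 0. Over the single lists 396 values kept call and direction, 68 lost the call (1 of them the red-cell list under its own score), 10 gained it and 24 turned; the platelet score difference kept its direction in its 11 alternatives, with an exact permutation p of 0.00794 to 0.0159 before adjustment (main adjusted p = 0.122). The cause was not tested. Counts of 0 allow up to 3 counts, 0.140 to 0.233 CPM.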

Other observations

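The tests in this part and the 6 lists in it were chosen only after the results were seen, except the 2 counts of regrouped libraries.

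Megakaryocytes, which shed platelets, carry surface and granule genes beyond the platelet list. Of 22 tested members of an added megakaryocyte list, 0 passed over all genes and 8 passed adjusted over the list alone: Gp1ba, a receptor of von Willebrand factor (log2 fold change 1.21), Gp6, a collagen receptor (1.148), Thbs1 (1.02), Mmrn1 (0.995), Selp (0.97), Rab27b (0.92) and Clec1b (0.74) were higher and Nfe2, a transcription factor of platelet formation, was lower (-0.52). The score had an exact permutation p of 0.00794 (adjusted p = 0.0476 over the 6 added lists), and the list an adjusted p of 0.0571 with an estimated correlation. The platelet score had the same exact permutation p, which was 0.122 when adjusted over the 46 fixed lists. Of its 25 members 4 also stand in the fixed lists and 0 in the platelet list. Erythroblast genes were negative in 18 of 18 members (Fech, the last enzyme of haem synthesis, -1.24; exact permutation p = 0.143). Marrow stroma (0.0556), neutrophil precursor (0.349), stem cell (0.540) and lymphoid precursor lists (0.603) did not differ by exact permutation p of their scores. Dntt, Rag1 and Rag2 stand in both the lymphoid precursor and the thymocyte list.

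The libraries had a structure that ran across the diets. The first component of 11587 protein-coding genes (28% of variance) followed the share of long intergenic non-coding RNA (r = 0.852, permutation p = 0.00093; within alternate 0.958 and within continuous 0.854), and a different share of nuclear or unspliced RNA may underlie it. It also followed the globin share (r = 0.815, permutation p = 0.00389, within alternate 0.547 and within continuous 0.880). Without the 2 libraries farthest in each measure, the permutation p was 0.0417 for globin and 0.00822 for long non-coding RNA. The relation with globin is partly built in, since red-cell genes are among the protein-coding genes. The 2 explanations were not separated. No biological explanation was tested.

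As many genes past the threshold came from 5 of 100 groupings of the libraries, the diet grouping itself among them, so chance was not excluded for the count of genes. The most, 997 genes, came from alternate 1 and 2 with continuous 2, 3 and 4 against the rest. Those libraries had the highest shares of long intergenic non-coding RNA (1.36% to 1.61%, against 0.711% to 1.21% in the rest). As many lists as the 15 of the diets came from 3 of 100 groupings, the diet grouping again among them, which argues against chance for that count at 0.05. The median grouping still gave 8 lists, so a call of a single list by camera at its preset correlation says little about diet.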
